A study of Mus musculus with 9 samples.

How the data were processed

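RNA sequencing was done by the study's submitters on subcutaneous adipose tissue of 9 C57BL/6 mice aged 24 weeks, with 3 mice in each of 3 genotype groups. The labels call the groups WT, Hete KO and Homo KO, and the knockout is of AGO1 in endothelial cells. Per the labels, the tissue was frozen, total RNA was extracted with Trizol and libraries followed a standard Illumina protocol. The whole tissue was sequenced, so endothelial transcripts were measured together with those of all other cells. Sex, litter, sequencing batch and the time of day of sampling are not given in the sources used here.

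The deposited files, one per library, hold 113193 transcripts each, with length and effective length in bases. Per the file headers, one column holds estimated counts (expected counts), which are fractional and are not normalized. Per the file headers, another column holds TPM, scaled by the authors to effective length and to the total of each library. The genome build was mm10 per the submitters' processing notes. The quantifier, its version and its settings are not given in the sources used here. Total estimated counts were between 20843427 and 28252001 per library.

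Transcripts were assigned to genes by identifier with GENCODE M21, whose coordinates are on GRCm38 (mm10). Of the 113193 transcripts, 111362 (98.38%) were matched, 109294 of them with the same version, and the 1831 unmatched transcripts, which held between 0.58 and 1.06% of the counts of a library, were left out. Estimated counts were summed to 35071 genes and rounded to whole numbers. Of these genes, 25581 had a count and 17968 passed edgeR's filter on low counts and were tested.

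The tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. All 9 libraries were fitted together with 1 coefficient per group and 6 residual degrees of freedom, by edgeR's quasi-likelihood F-test after TMM normalization, with a prior count of 0.125 for fold changes and 2 for log2 levels. The tests were two-sided, and p values were adjusted over all tested genes by the Benjamini-Hochberg method, with 0.05 as threshold. Homo KO was compared with WT, Hete KO with WT, and Homo KO with Hete KO. Levels are normalized CPM, given as mean and SD over n = 3 libraries, and the SE is that of the log2 fold change.

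In all, 36 gene lists were tested. They cover thermogenic genes, beige-selective genes, nuclear-encoded respiratory chain subunits, mitochondrially encoded genes, fatty acid oxidation, the TCA cycle, lipogenesis, cholesterol synthesis, triglyceride storage and lipolysis, adipocyte markers and insulin signalling. They further cover endothelial, pro-angiogenic, anti-angiogenic, hypoxia, macrophage, inflammation, interferon, antigen presentation, T and NK cell, B cell and lymph node, and neutrophil and mast cell genes. The others hold extracellular matrix, progenitor and fibroblast, mural and smooth muscle, skeletal muscle, mammary epithelium, skin keratinocyte, nerve and Schwann cell, blood, microRNA machinery, immediate early, heat shock, circadian, cell cycle and sex-linked genes. Each list was tested with camera at a preset correlation of 0.01 between genes, with camera at a correlation estimated per list, and with fry. Camera compares a list with all other genes, while fry tests whether its genes move on balance in 1 direction. List p values were adjusted over the 36 lists. Counts within a list are given over all genes and adjusted over the list alone.

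The comparisons, tests, lists, thresholds and the rule for named genes were fixed before the data were examined. The rule takes Ago1, then 8 genes of interest to the study's subject (Thbs1, Ucp1, Cidea, Ppargc1a, Vegfa, Pecam1, Adipoq and Lep). It adds per comparison up to 10 higher and 10 lower genes with the smallest adjusted p, a mean of at least 1 CPM and groups that do not overlap. Where no gene passed in a direction, the 3 with the smallest p that meet the same conditions on CPM and overlap are given and said not to pass. Predicted and unnamed genes, pseudogenes and mitochondrial tRNA and rRNA genes are left out of this choice. For each list that was called or had a member past the threshold, the rule allows up to 4 members with the smallest p, of which the 2 smallest are printed here. A few genes that the rule takes are not reported here.

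The alternatives fixed in advance were DESeq2, RLE and upper-quartile normalization, no filter and a stricter filter (1 CPM in 3 libraries), an offset for transcript length, a robust fit, a fit of the 2 compared groups only, the replicate number as a block, 1 surrogate variable, limma on log2 TPM with pseudocounts of 0.5 and 0.1, and leaving out each library in turn. Chosen after the data were seen were 3 settings for transcripts of other tissues and the comparison of both KO groups together with WT. The first setting leaves out libraries whose skeletal muscle list held over 1% of counts. The second leaves out libraries in which a list of 24 liver genes, also written after the data were seen, held over 0.1%. The third adds both list scores as covariates. With the same covariates, a linear model was fitted to the mean score of several lists per library. Also chosen then was a division of the WT libraries between the 2 comparisons against WT.

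Pearson correlation between replicates of a group was between 0.941 and 0.977 on the log2 scale, and between libraries of different groups between 0.912 and 0.971. Some WT libraries were closer to KO libraries than to each other. The WT pairs had 0.945, 0.941 and 0.941. WT 1 and Hete KO 1 had 0.967, and WT 3 had 0.960, 0.958 and 0.956 with Homo KO 1, 2 and 3. For WT 2 the correlations with KO libraries were lower, between 0.912 and 0.931. The spread between replicates exceeded counting error in each group, with a chi-square per degree of freedom of at least 17.1, so the replicates and not the depth set the precision. The method was tested on simulated data made from these libraries, with 200 changed genes and the cell cycle list raised as well. At a 2-fold change, edgeR recovered 37% of the changed genes in the Homo KO and WT libraries, 40% in the Hete KO and WT libraries and 37% in the Homo KO and Hete KO libraries. At a 4-fold change it recovered 81%, 80% and 87%, and 5.56%, 6.20% and 3.13% of its calls were false. DESeq2 made 26.6%, 20.7% and 18.6% false calls in the same simulations. Each comparison had a single draw, in which each gene was drawn on its own with the same spread for all libraries. Transcripts that rise together in single libraries were not simulated, so these shares of false calls need not hold for the real data.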

Results

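Transcript levels were measured in 9 libraries of mouse subcutaneous fat, 3 from WT animals, 3 from Hete KO animals and 3 from Homo KO animals. The total estimated counts were 23522907, 23235249 and 28252001 in WT 1, 2 and 3. They were 27419341, 26328951 and 20894437 in Hete KO 1, 2 and 3, and 20843427, 21612379 and 25623210 in Homo KO 1, 2 and 3. Scd1, a fatty acid desaturase of lipid synthesis, was the most abundant gene in all 9 libraries, with between 2.93 and 8.19% of the counts. Mitochondrially encoded genes took 3.10, 2.10 and 2.93% of the counts in WT, 3.58, 4.11 and 4.24% in Hete KO, and 3.53, 3.87 and 3.59% in Homo KO. Values after ± are SDs over the 3 libraries of a group unless an SE is named.

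Skeletal muscle transcripts were abundant in 3 libraries. The list of 18 muscle genes took 3.34% of the counts in WT 1, 2.58% in WT 2 and 8.02% in Hete KO 2, against 0.0152% in WT 3, 0.396% in Hete KO 1, 0.0947% in Hete KO 3, and 0.0711, 0.0365 and 0.00825% in Homo KO 1, 2 and 3. Myh4, a myosin heavy chain of fast muscle fibres, had 5098, 4180 and 16032 CPM in those 3 libraries and between 6.98 and 566 CPM in the other 6. Liver transcripts were present in WT 2 and WT 3, where 24 liver genes took 0.169 and 0.153% of the counts. The same genes took between 0.00346 and 0.00999% in the other 7 libraries. Alb, which encodes serum albumin, had 633 CPM in WT 2 and 609 in WT 3 and between 6.43 and 46.9 elsewhere.

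**Figure D1:**
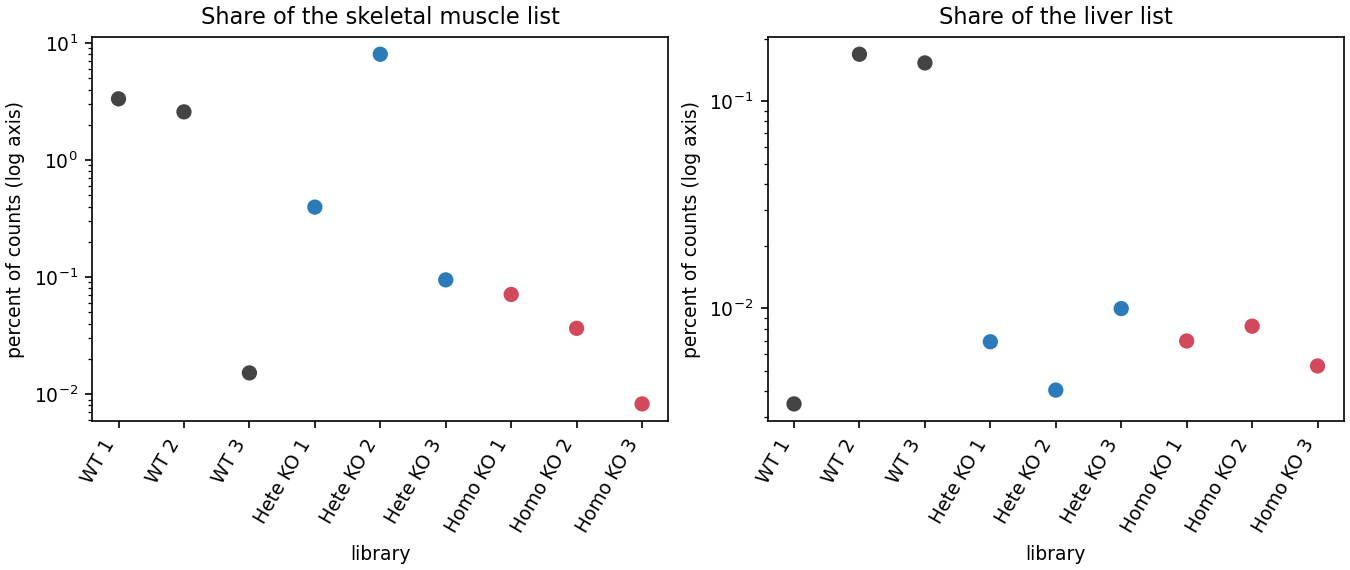
Percent of the counts of each library taken by the 18 skeletal muscle genes and the 24 liver genes, on a log axis, with 1 point per library. WT 1, WT 2 and Hete KO 2 held 3.34, 2.58 and 8.02% muscle transcripts, and WT 2 and WT 3 held 0.169 and 0.153% liver transcripts.

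Ago1, the targeted gene, encodes an Argonaute protein that binds microRNAs, and lies on the minus strand of chromosome 4 at 126435012 to 126468583 (mm10, ENSMUSG00000041530.16). Its level was 65.7 ± 3.66 CPM in WT, 57.0 ± 5.04 in Hete KO and 48.9 ± 20.1 in Homo KO (n = 3 each). All 6 KO libraries lay below all 3 WT libraries, with 69.9, 63.8 and 63.4 CPM in WT 1, 2 and 3, 51.2, 59.7 and 60.1 in Hete KO 1, 2 and 3, and 62.2, 58.6 and 25.8 in Homo KO 1, 2 and 3. The log2 fold change was -0.43 (SE 0.265, edgeR adjusted p = 0.441) in Homo KO against WT and -0.21 (SE 0.264, adjusted p = 0.699) in Hete KO against WT, so neither difference passed the test. Between Homo KO and Hete KO it was -0.22 (SE 0.265, adjusted p = 0.969). Over the 6 KO libraries the mean was 52.9 ± 13.8 CPM. A two-sided exact permutation test of the difference in means from the 3 WT libraries gave p = 0.119 over 84 arrangements. It rests on the means, and so on the low value of Homo KO 3, and not on the order of the libraries. The low mean of the Homo KO group came from 1 library. Without Homo KO 3 the log2 fold change was -0.11 against WT and 0.07 against Hete KO. The 7227-base Ago1 transcript had 475 estimated counts in Homo KO 3 and between 906 and 1603 in the other 8 libraries.

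**Figure D2:**
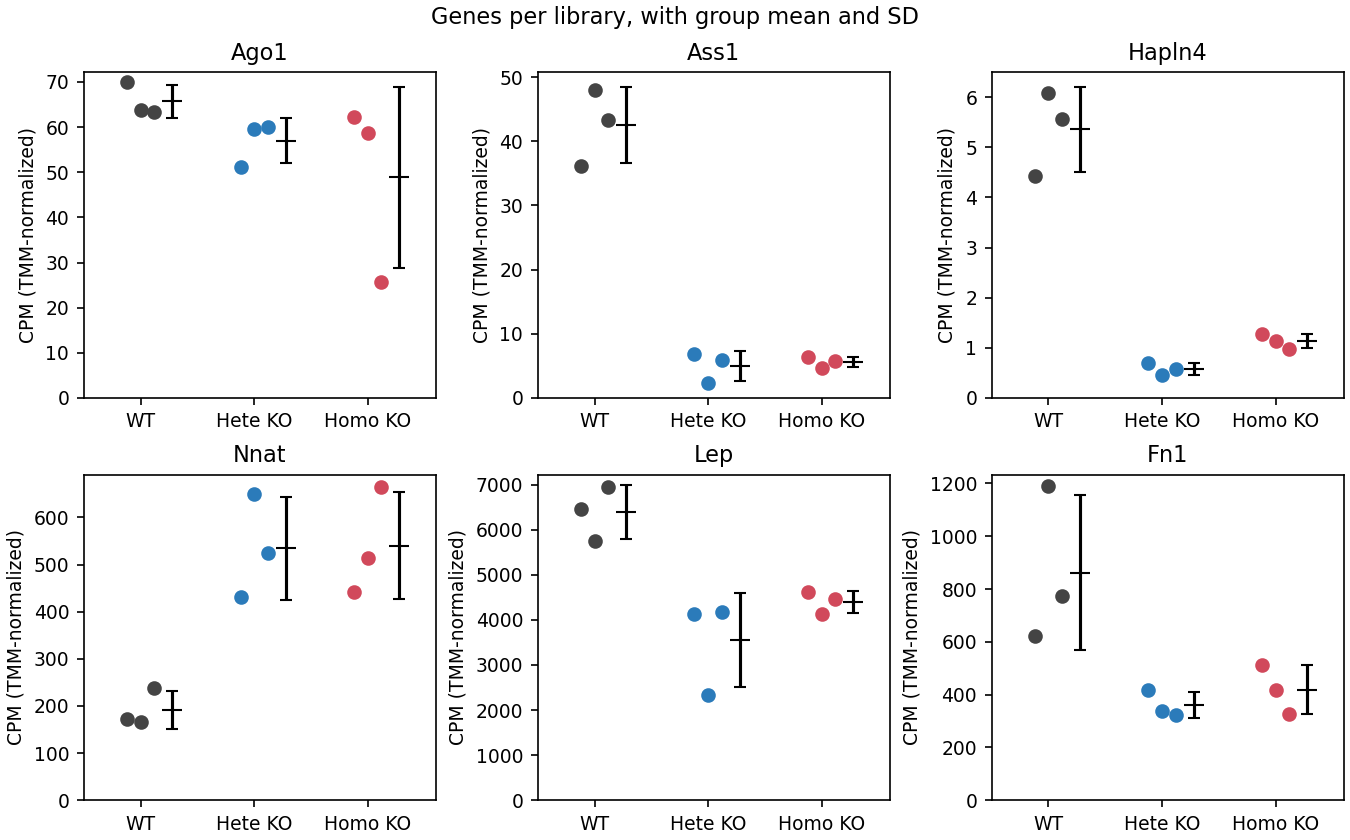
Normalized CPM of Ago1, Ass1, Hapln4, Nnat, Lep and Fn1, with 1 point per library and the mean and SD of each group (n = 3). Ass1 averaged 42.5 CPM in WT, 5.03 in Hete KO and 5.59 in Homo KO, while Ago1 averaged 65.7, 57.0 and 48.9.

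Homo KO was compared with WT to ask which transcripts differ in the fat of the animals labelled as homozygous knockouts. The smallest adjusted p was that of Ass1, which encodes argininosuccinate synthase of arginine synthesis (chromosome 2, 31470207 to 31520672). It had 5.59 ± 0.825 CPM in Homo KO and 42.5 ± 5.95 in WT, a log2 fold change of -2.93 (SE 0.330, adjusted p = 0.0920, n = 3 per group). Hapln4, a link protein of hyaluronan matrix, had 1.13 ± 0.141 against 5.36 ± 0.851 CPM (-2.24), and Bmp1, a procollagen C-proteinase, 42.7 ± 1.82 against 69.5 ± 6.68 CPM (-0.70). On the other side, Nnat, which encodes neuronatin, had 540 ± 114 CPM in Homo KO and 192 ± 39.9 in WT (1.49, SE 0.214). Gulp1, an engulfment adaptor, had 24.8 ± 2.17 against 13.0 ± 0.214 CPM (0.93), and Zfp970 113 ± 12.03 against 58.3 ± 8.72 CPM (0.96). The adjusted p was 0.126 for Hapln4, Bmp1, Nnat, Gulp1 and Zfp970. None of these 6 genes passed the test. They are the 3 higher and 3 lower genes with the smallest p among those whose groups do not overlap. That every Homo KO library lay beyond every WT library was thus a condition of their choice. By edgeR, 0 of 17968 genes passed in either direction, 2952 had an unadjusted p under 0.05 against 898 by chance, and 22.1% had groups that did not overlap, against 10% by chance. Both chance values are averages and give no spread where genes move together. Other splits of these 6 libraries into 3 and 3 gave between 272 and 1728 genes at an unadjusted p under 0.05. DESeq2 called 271 genes higher and 362 lower, and limma on log2 TPM called 0. Without WT 1, edgeR called 19 genes higher and 134 lower. It called 0 and 1 without WT 2, and 0 and 2 without Hete KO 2. With the 3 muscle-transcript libraries left out, which leaves WT 3 as the only WT library, it called 3 higher and 38 lower, and without the liver-transcript libraries, 1 and 1.

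Among the metabolic lists in Homo KO against WT, cholesterol synthesis was lower by camera, with a median log2 fold change of -0.48 over 20 genes (adjusted p = 9.05e-07, and adjusted p = 0.559 with an estimated correlation). In it, 6 genes were lower when adjusted over the list alone and 0 over all genes. Fdps, which makes farnesyl diphosphate, had 21.2 ± 3.16 against 37.1 ± 6.15 CPM (-0.81, adjusted p = 0.154). Mitochondrially encoded genes were higher, with a median of 0.51 over 13 genes (adjusted p = 2.14e-06, and adjusted p = 0.559 with an estimated correlation). None of the 13 passed alone, with mt-Nd5 at 0.59 (adjusted p = 0.218) and mt-Atp8 at 0.80 (adjusted p = 0.222). Adipocyte markers were higher with a median of 0.34 over 19 genes (adjusted p = 1.01e-05, and adjusted p = 0.559 with an estimated correlation). In that list 3 genes were higher when adjusted over the list alone and 0 over all genes, with Nnat first and Cfd, which encodes adipsin, at 708 ± 229 against 211 ± 145 CPM (1.75, adjusted p = 0.197). Insulin signalling had a median of 0.14 (adjusted p = 0.0230, and 0.559 with an estimated correlation), with Pde3b at 0.82 (adjusted p = 0.184) and Irs1, the insulin receptor substrate, at 0.77 (adjusted p = 0.212). The TCA cycle list had a median of 0.13 (adjusted p = 0.0366, and adjusted p = 0.793 with an estimated correlation), with Sdha at 0.43 (adjusted p = 0.218) and Idh2 at 0.31 (adjusted p = 0.252). Cholesterol synthesis stayed called without the muscle-transcript libraries (-0.49), without the liver-transcript libraries (-0.36) and with muscle and liver scores as covariates (-0.60). Without the muscle-transcript libraries the calls of the adipocyte, insulin and TCA lists ended, at medians of 0.09, 0.07 and 0.08. With the covariates the calls of the adipocyte, mitochondrial, insulin and TCA lists ended, at 0.15, 0.07, 0.02 and 0.18, and without the liver-transcript libraries that of the mitochondrial list ended at 0.33. The insulin call also ended with 1 surrogate variable (0.06) and without WT 1 (0.16), WT 2 (0.10) or Homo KO 3 (0.11), and the TCA call without WT 1 (0.12), Homo KO 2 (0.12) or Homo KO 3 (0.06).

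Among lists of cell types and tissue state in Homo KO against WT, cell cycle genes were lower, with a median of -0.72 over 20 genes (camera adjusted p = 1.38e-08, and adjusted p = 0.559 with an estimated correlation). Adjusted over the list alone 6 were lower, over all genes 0, with the mitotic kinase gene Aurkb at 1.92 ± 0.289 against 4.43 ± 0.542 CPM (-1.20, adjusted p = 0.154) and Cenpf at -0.87 (adjusted p = 0.162). Macrophage genes were lower, with a median of -0.61 over 22 genes (adjusted p = 3.27e-07, and adjusted p = 0.559 with an estimated correlation). None passed alone, and the complement genes C1qa and C1qc had -0.87 (adjusted p = 0.174) and -0.62 (adjusted p = 0.205). Extracellular matrix genes had a median of -0.37 over 28 genes (adjusted p = 3.32e-05, and adjusted p = 0.632 with an estimated correlation), and progenitor and fibroblast genes -0.26 over 18 (adjusted p = 0.00147, and 0.559 with an estimated correlation). Adjusted over the list alone, the matrix list held 2 lower genes, Col12a1 at 34.9 ± 7.70 against 159 ± 44.6 CPM (-2.19) and Fn1, which encodes fibronectin, at 419 ± 91.9 against 862 ± 293 CPM (-1.04), while over all genes it held 0. The progenitor list held 4 lower and 1 higher when adjusted over the list alone and 0 over all genes, among them Dpp4, a marker of adipose progenitors, at -1.25 (adjusted p = 0.126) and F3, which encodes tissue factor, at 1.04 (adjusted p = 0.154). Heat shock genes had a median of -0.26 (adjusted p = 0.0109, and adjusted p = 0.559 with an estimated correlation), with 3 lower when adjusted over the list alone, among them Hsph1 at -0.47 (adjusted p = 0.162) and Sdf2l1 at -0.69 (adjusted p = 0.201). Inflammation genes had a median of -0.56 (adjusted p = 0.0131, and adjusted p = 0.559 with an estimated correlation), with the chemokine gene Ccl5 at 1.22 (adjusted p = 0.223) and Lcn2, which encodes lipocalin 2, at -1.44 (adjusted p = 0.225). Interferon genes were higher with a median of 0.24 (adjusted p = 0.00665, and 0.559 with an estimated correlation), with Ifit3 at 0.50 and Gbp3 at 0.28. B cell and lymph node genes had a median of 0.64 (adjusted p = 0.0179, and adjusted p = 0.718 with an estimated correlation), with 2 higher when adjusted over the list alone, the B cell genes Cr2 (0.83) and Cd79a (2.34). The summed share of this list went the other way, at 0.0647, 0.0586 and 0.0664% of the counts in WT 1, 2 and 3. It was 0.0406, 0.0424 and 0.0402% in Homo KO 1, 2 and 3. The median weighs each gene alike, so it does not show a higher total of these transcripts. Blood genes had a median of -0.67 (adjusted p = 0.00378, and adjusted p = 0.559 with an estimated correlation), with the haemoglobin genes Hbb-bt at -1.39 and Hba-a1 at -1.05. Skeletal muscle genes had a median of -5.52 over 18 genes (adjusted p = 1.38e-08, and adjusted p = 0.559 with an estimated correlation), 17 of them lower when adjusted over the list alone and 0 over all genes. Tnnc2 had 1.81 ± 1.18 against 99.3 ± 85.5 CPM and Ckm 4.53 ± 3.45 against 348 ± 300 CPM, with the WT level in WT 1 and WT 2.

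In Homo KO against WT the macrophage, inflammation and blood calls ended without the muscle-transcript libraries, at medians of -0.09, 0.02 and -0.51, and with the muscle and liver covariates, at -0.21, -0.39 and -0.57. The skeletal muscle median turned to 1.54 without those libraries, was -0.08 with the covariates and 0.13 with 1 surrogate variable. The interferon, B cell and progenitor calls ended without the liver-transcript libraries, at 0.13, 0.39 and -0.25. By camera 15 of the 36 lists were called, 6 higher and 9 lower, 9 with the covariates and 0 with an estimated correlation, while fry called 0 in 1 direction and 14 for change in either direction. The length offset ended the blood (-0.11) and heat shock (-0.24) calls, 1 surrogate variable the B cell (0.14) and inflammation (-0.40) calls, and the covariates the B cell call (-0.04). The inflammation call also ended without WT 1 (-0.32) or Homo KO 3 (-0.40), the interferon call without WT 3 (0.15) or Homo KO 1 (0.18), the heat shock call without WT 3 (-0.21), and the B cell call without WT 2 (0.44), WT 3 (0.61) or Homo KO 3 (0.39).

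In Homo KO against WT the lists closest to the study's subject that were not called by camera were thermogenic genes, with a median of -0.28 over 25 genes (adjusted p = 0.164), endothelial genes at 0.09 over 22 (adjusted p = 0.476), pro-angiogenic genes at 0.13 (adjusted p = 0.246) and anti-angiogenic genes at 0.11 (adjusted p = 0.712). Adjusted over the list alone, the thermogenic list held 2 higher and 3 lower genes, over all genes 0. Also not called were beige-selective genes at 0.09 (adjusted p = 0.734), nuclear respiratory chain at 0.01 (0.464), fatty acid oxidation at 0.04 (0.261), lipogenesis at 0.01 (0.948), triglyceride storage and lipolysis at 0.13 (0.0939) and hypoxia at -0.07 (0.948). Antigen presentation had a median of -0.17 (adjusted p = 0.0528), T and NK cells 0.31 (0.0848), neutrophils and mast cells -0.28 (0.164), and mural and smooth muscle cells -0.19 (0.168). The microRNA machinery had a median of 0.09 (adjusted p = 0.464), immediate early genes -0.15 (0.261), circadian genes 0.29 (0.164) and sex-linked genes 0.10 (0.464). Mammary epithelium, nerve and skin genes had medians of 0.09, 0.11 and 0.04 (adjusted p = 0.355, 0.712 and 0.948). The mean and the test pointed down against a positive median for beige-selective genes (mean -0.09) and skin genes (mean -0.37), and the lipogenesis mean was just below 0.

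None of the 8 genes fixed for their link to the study's subject passed in Homo KO against WT. Lep, which encodes leptin, had 4399 ± 251 CPM in Homo KO and 6389 ± 604 in WT, a log2 fold change of -0.54 (SE 0.210, adjusted p = 0.257). Ppargc1a, a coactivator of mitochondrial genes, had 22.3 ± 4.62 against 11.9 ± 2.22 CPM (0.91, adjusted p = 0.192). Adipoq, which encodes adiponectin, was at 1432 ± 172 against 1120 ± 344 CPM (0.35, adjusted p = 0.419), and the angiogenic factor gene Vegfa at 230 ± 6.93 against 201 ± 9.53 CPM (0.20, adjusted p = 0.541). The endothelial marker Pecam1 was at 211 ± 35.7 against 197 ± 23.1 CPM (0.10, adjusted p = 0.771, and -0.01 without Homo KO 1). Thbs1, which encodes the angiogenesis inhibitor thrombospondin 1, was at 99.7 ± 28.01 against 113 ± 42.0 CPM (-0.18, adjusted p = 0.797, and 0.08 without WT 1). Ucp1, the uncoupling protein of thermogenic fat, had 4.15 ± 2.98 CPM in Homo KO and 58.5 ± 95.2 in WT (-3.82, adjusted p = 0.307). Its WT level lay in 1 library, with 168 CPM in WT 2 against 6.01 in WT 1 and 1.14 in WT 3, and the log2 fold change was 0.23 without WT 2. Cidea, a lipid droplet protein of thermogenic fat, had no direction, at 12.8 ± 5.07 against 12.8 ± 12.8 CPM, and its log2 fold change ran from -0.44 without WT 1 to 1.22 without WT 2.

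Hete KO was compared with WT to ask which transcripts differ in the fat of the animals labelled as heterozygous knockouts. Hapln4 fell from 5.36 ± 0.851 CPM in WT to 0.584 ± 0.120 in Hete KO (log2 fold change -3.18, SE 0.301, adjusted p = 0.0191, n = 3 per group), and Ass1 fell from 42.5 ± 5.95 to 5.03 ± 2.33 CPM (-3.08, SE 0.332, adjusted p = 0.0251). The 3 WT libraries held 36.2, 48.0 and 43.3 CPM of Ass1, and WT 1, with the first of these values, held few liver transcripts. Serpina3m, of a family of protease inhibitors, fell with a log2 fold change of -2.74, as did Bmp1 with -0.92 (adjusted p = 0.0251 each). Slc6a6, the taurine transporter, fell from 386 ± 26.6 to 170 ± 16.7 CPM (-1.19, adjusted p = 0.0319). Cenpe, a motor protein of mitosis, had -1.85 (adjusted p = 0.0326) and the histone gene Hist1h2af -1.93 (adjusted p = 0.0325), while Tril and C1qtnf6 had -1.28 and -1.21 (adjusted p = 0.0332). Among genes that rose, Nnat went from 192 ± 39.9 to 534 ± 110 CPM (1.48, SE 0.214, adjusted p = 0.0364), Il17rb, a receptor subunit for interleukin 25, from 1.91 ± 0.261 to 7.06 ± 2.33 CPM (1.88, adjusted p = 0.0385) and Gulp1 from 13.0 ± 0.214 to 27.2 ± 3.67 CPM (1.06, adjusted p = 0.0254). The noncoding RNA gene Snhg11 had 1.10 and Thap2 0.92 (adjusted p = 0.0251), Slc44a3 1.02 (adjusted p = 0.0254), and Zfp809, a repressor of retroviral elements, 1.10 (adjusted p = 0.0325). Pcf11, which acts in cleavage of mRNA 3' ends, had 0.77 (adjusted p = 0.0325), the laminin gene Lama3 1.14 (adjusted p = 0.0332) and Rad9b 1.38 (adjusted p = 0.0340). In all, 27 genes were higher and 48 lower of 17968 by edgeR, 3927 had an unadjusted p under 0.05, and 24.7% had groups that did not overlap, against 10% by chance. Other splits of these libraries into 3 and 3 gave between 262 and 2095 genes at an unadjusted p under 0.05. DESeq2 called 599 higher and 1011 lower, 73 of the 75 genes among them, and limma called 0 or 4 higher and 0 lower. The counts higher and lower were 124 and 307 without WT 1, 0 and 1 without WT 2, 12 and 14 without WT 3, 357 and 601 without Hete KO 1, 0 and 1 without Hete KO 2 and 0 and 0 without Hete KO 3. Leaving out a library of the group outside the comparison gave 0 and 0 without Homo KO 1, 0 and 0 without Homo KO 2 and 0 and 2 without Homo KO 3. They were 1 and 10 without the muscle-transcript libraries, 1 and 0 without the liver-transcript libraries and 0 and 0 with both as covariates. All 75 genes kept their sign in the fits that left out libraries or used the covariates.

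Matrix, macrophage and cell cycle genes were lower by camera in Hete KO than in WT. The extracellular matrix list had a median log2 fold change of -0.76 over 28 genes (adjusted p = 2.96e-17, and adjusted p = 0.364 with an estimated correlation), with 25 lower when adjusted over the list alone and 0 over all genes. Fn1 had 360 ± 50.4 against 862 ± 293 CPM (-1.26, adjusted p = 0.0591) and the collagen gene Col1a2 461 ± 112 against 929 ± 210 CPM (-1.01, adjusted p = 0.0597). Macrophage genes had a median of -1.20 over 22 genes (adjusted p = 1.06e-16, and adjusted p = 0.364 with an estimated correlation). Of these 19 were lower when adjusted over the list alone and 1 over all genes, C1qc, which fell from 35.7 ± 8.44 to 15.9 ± 2.41 CPM (-1.17, adjusted p = 0.0426), with C1qb at -1.39 (adjusted p = 0.0574). Cell cycle genes had a median of -1.08 over 20 (adjusted p = 1.10e-11, and adjusted p = 0.364 with an estimated correlation). Adjusted over the list alone 15 were lower and over all genes 1, Aurkb, which fell from 4.43 ± 0.542 to 1.36 ± 0.132 CPM (-1.70, adjusted p = 0.0403), with Cenpf at -1.19 (adjusted p = 0.0526). In the progenitor and fibroblast list, with a median of -0.54 over 18 (adjusted p = 1.62e-05, and 0.364 with an estimated correlation), 10 were lower and 1 higher when adjusted over the list alone. Over all genes 1 passed, Dpp4, which fell from 35.0 ± 9.20 to 15.8 ± 1.66 CPM (-1.15, adjusted p = 0.0490), with Sfrp4 at -1.41 (adjusted p = 0.0526). Antigen presentation had a median of -0.54 over 13 (adjusted p = 2.30e-05, and 0.423 with an estimated correlation), with 7 lower when adjusted over the list alone and 1 over all genes. That gene was H2-DMb1, which acts in peptide loading of MHC class II, and it fell from 26.8 ± 4.20 to 7.86 ± 3.01 CPM (-1.77, adjusted p = 0.0426), with H2-Eb1 at -0.64 (adjusted p = 0.0757). Inflammation genes had a median of -0.62 (adjusted p = 1.52e-04, and 0.423 with an estimated correlation), with 3 lower when adjusted over the list alone, Lcn2 at -3.01 (adjusted p = 0.0526) and Icam1 at -0.56 (adjusted p = 0.0821). Blood genes had a median of -0.99 (adjusted p = 0.00580), with Hbb-bs at -1.33 and Hbb-bt at -1.52, and heat shock genes -0.28 (adjusted p = 0.0280), with Hspa5 at -0.61 and Hsph1 at -0.30. For blood and heat shock genes the adjusted p was 0.423 with an estimated correlation. By camera 15 of the 36 lists were called, 6 higher and 9 lower, with 9 called without WT 1 and 0 with an estimated correlation. Fry called 28 for change in either direction and 4 in 1 direction, each with an adjusted p of 0.0390, namely matrix, progenitor, heat shock and cell cycle. The medians for macrophage, matrix and cell cycle genes were -1.09, -0.70 and -0.999 with the muscle and liver covariates and -1.19, -0.65 and -1.22 without the liver-transcript libraries. Neither setting ended a list call. Without the muscle-transcript libraries, with WT 3 as the only WT library, they were -0.40, -0.45 and -0.54. The inflammation (-0.11) and blood (-0.997) calls then ended. That fit did not even out muscle transcripts, since its skeletal muscle median was 4.45, against 0.64 with all libraries. The blood call also ended without Hete KO 1 (-0.82), and the heat shock call without WT 1 (-0.28), WT 3 (-0.25) or Hete KO 2 (-0.27).

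Mitochondrial and adipocyte lists were higher by camera in Hete KO than in WT. Mitochondrially encoded genes had a median of 0.78 over 13 genes (adjusted p = 1.08e-08, and adjusted p = 0.423 with an estimated correlation), with 11 higher when adjusted over the list alone and 0 over all genes, among them mt-Cytb at 0.98 and mt-Nd5 at 0.78 (adjusted p = 0.0767 each). Adipocyte markers had a median of 0.27 over 19 (adjusted p = 0.00100, and adjusted p = 0.565 with an estimated correlation), with 5 higher and 1 lower when adjusted over the list alone. Nnat was the member past the threshold over all genes, and Lep, the lower one, had 3546 ± 1044 against 6389 ± 604 CPM (-0.85, adjusted p = 0.0767). The TCA cycle list had a median of 0.24 (adjusted p = 0.00235, and adjusted p = 0.761 with an estimated correlation), with Sdha at 0.57 and Pdha1 at 0.49, and the nuclear respiratory chain 0.10 over 46 genes (adjusted p = 0.0406, and adjusted p = 0.866 with an estimated correlation), with Sdha and Cox7a2 (0.49). Insulin signalling had a median of 0.14 (adjusted p = 0.0290, and adjusted p = 0.533 with an estimated correlation), with 6 higher when adjusted over the list alone, Pde3b at 0.88 (adjusted p = 0.0770) and Irs1 at 0.93 (adjusted p = 0.0819) among them. Circadian genes had a median of 0.56 (adjusted p = 0.00641, and adjusted p = 0.533 with an estimated correlation), with 4 higher and 1 lower when adjusted over the list alone, Hlf at 1.17 (adjusted p = 0.0696) and Ciart at 1.31 (adjusted p = 0.0865). The circadian list was included as a sign of the time of sampling, which is not given. In any of the comparisons, a difference in that time and the genotype cannot be told apart by it. Cholesterol synthesis was lower with a median of -0.48 over 20 (adjusted p = 2.21e-05, and adjusted p = 0.423 with an estimated correlation). In it 10 genes were lower and 1 higher when adjusted over the list alone and 0 over all genes, with Dhcr7 at -0.75 (adjusted p = 0.0666). With the muscle and liver covariates all of these lists stayed called, the adipocyte list at 0.31 and the mitochondrially encoded list at 0.53. Without the muscle-transcript libraries, where WT 3 alone stands for WT, the adipocyte (0.04), TCA (0.07), respiratory chain (-0.09), insulin (0.09) and circadian (0.21) calls ended, while the mitochondrially encoded list (0.54) and cholesterol synthesis (-0.45) stayed called. Without WT 1 the adipocyte (0.27), TCA (0.22), respiratory chain (0.10), insulin (0.12) and circadian (0.47) calls ended, without WT 2 the insulin call (0.11), and without Hete KO 2 the TCA (0.14), respiratory chain (-0.03) and circadian (0.22) calls. The length offset ended the respiratory chain call (0.07).

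**Figure D3:**
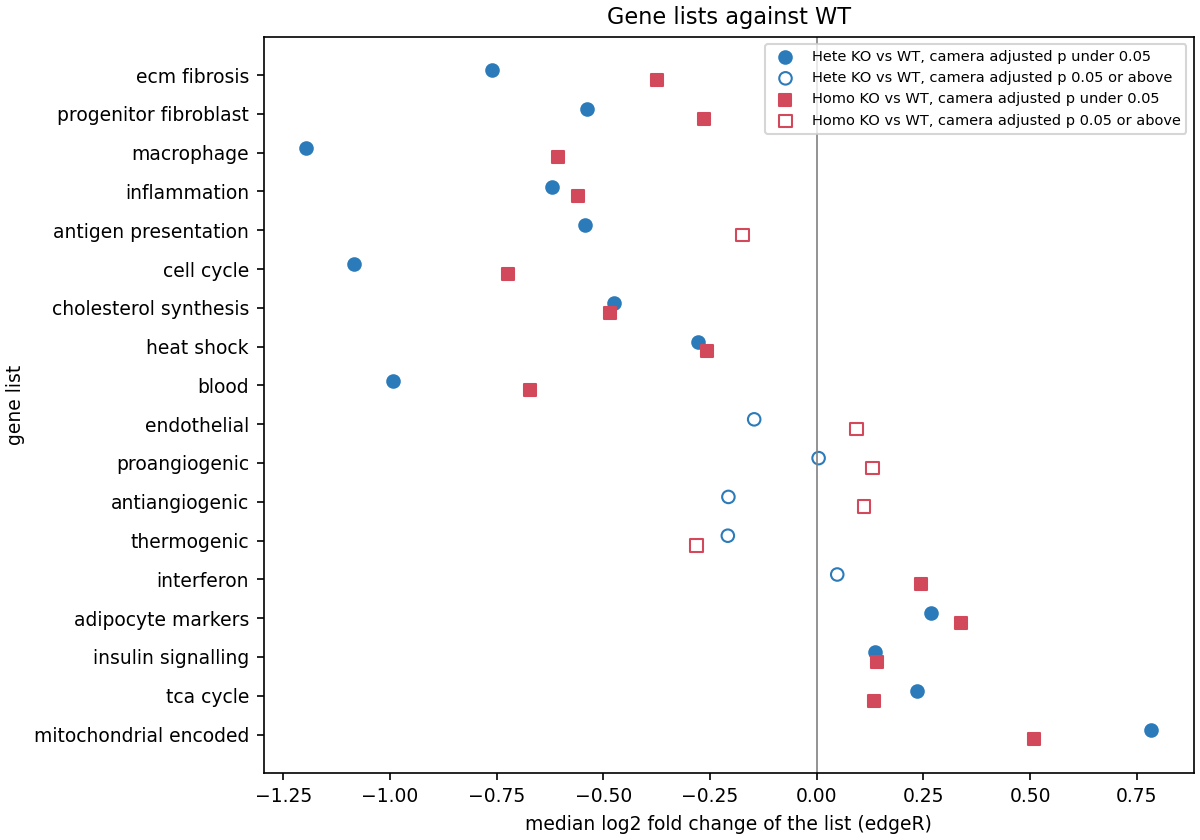
Median log2 fold change of 18 gene lists in Hete KO and in Homo KO against WT, with filled points where camera gave an adjusted p under 0.05. Macrophage genes had medians of -1.20 and -0.61 and mitochondrially encoded genes 0.78 and 0.51, and no list was called with an estimated correlation.

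Thermogenic genes had a median of -0.21 in Hete KO against WT (camera adjusted p = 0.661), endothelial genes -0.15 (adjusted p = 0.174), pro-angiogenic genes 0.00 (0.780), anti-angiogenic genes -0.21 (0.121), hypoxia genes 0.01 (0.780) and skeletal muscle genes 0.64 (0.471). The median was above 0 and the mean below for pro-angiogenic (-0.08), interferon (0.05 and -0.11), T and NK cell (0.10 and -0.11), skin (0.24 and -0.30) and hypoxia genes. For mammary genes the median was -0.09 and the test pointed up. None of the 8 fixed genes passed. Ppargc1a had 25.2 ± 9.02 CPM in Hete KO and 11.9 ± 2.22 in WT (1.09, SE 0.260, adjusted p = 0.0721), and Vegfa 271 ± 62.5 against 201 ± 9.53 CPM (0.43, adjusted p = 0.150). Thbs1 was at 79.7 ± 19.8 against 113 ± 42.0 CPM (-0.51, adjusted p = 0.358), Pecam1 at 175 ± 8.74 against 197 ± 23.1 CPM (-0.17, adjusted p = 0.525) and Adipoq at 1397 ± 161 against 1120 ± 344 CPM (0.32, adjusted p = 0.404). Ucp1 was at 10.9 ± 15.9 CPM (-2.42, adjusted p = 0.412, and 1.64 without WT 2) and Cidea at 16.1 ± 9.22 CPM (0.34, adjusted p = 0.819, -0.09 without WT 1 and -0.26 without Hete KO 2).

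Homo KO was compared with Hete KO to ask whether the fat of the 2 knockout groups differs. Of the genes whose groups do not overlap, the 3 with the smallest p on each side were taken. None of them passed (adjusted p = 0.899 each, n = 3 per group). Slc40a1, the iron exporter ferroportin, had 31.9 ± 3.88 CPM in Homo KO and 17.9 ± 3.69 in Hete KO (0.83, SE 0.178), Tmem86a 14.2 ± 1.68 against 7.53 ± 1.09 CPM (0.91) and Marcksl1 8.56 ± 0.582 against 4.72 ± 0.473 CPM (0.86). Hspb7, a small heat shock protein of muscle, had 10.3 ± 1.48 against 29.2 ± 16.3 CPM (-1.50), Clca3a1 1.10 ± 0.342 against 2.98 ± 0.505 CPM (-1.43) and Eva1c 4.61 ± 1.27 against 9.80 ± 2.31 CPM (-1.09). By edgeR 0 genes were higher and 0 lower, with 978 at an unadjusted p under 0.05 against 898 by chance and 11.4% with groups that did not overlap, against 10% by chance. Other splits of these libraries into 3 and 3 gave between 251 and 1432 genes at an unadjusted p under 0.05. DESeq2 called 0 higher and 2 lower, and limma called 0 with a pseudocount of 0.5 and 2 higher and 4 lower with 0.1.

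Camera placed matrix, macrophage and endothelial lists higher in Homo KO than in Hete KO, among 16 of 36 lists called, 11 higher and 5 lower. Matrix genes had a median of 0.41 over 28 genes (adjusted p = 2.28e-14, and adjusted p = 0.477 with an estimated correlation), with Dcn, which encodes decorin, at 356 ± 8.71 against 277 ± 28.5 CPM (0.36) and Loxl2 at 0.54. Macrophage genes had a median of 0.58 (adjusted p = 4.53e-09, and adjusted p = 0.608 with an estimated correlation), with Tyrobp at 0.80 and C1qc at 0.55. Endothelial genes had a median of 0.20 (adjusted p = 5.83e-04, and adjusted p = 0.742 with an estimated correlation), with Sox18 at 9.88 ± 2.47 against 5.63 ± 0.835 CPM (0.81) and Erg at 0.71, both endothelial transcription factors. Anti-angiogenic genes had 0.23 (adjusted p = 0.00124, and 0.477 with an estimated correlation), with Vash1 at 0.72 and Timp2 at 0.44. Pro-angiogenic genes had 0.11 (adjusted p = 0.0305, and 0.739 with an estimated correlation), with Apln at 39.7 ± 8.21 against 19.3 ± 6.59 CPM (1.03) and its receptor Aplnr at 0.76. Interferon genes had 0.27 (adjusted p = 1.20e-06, and 0.477 with an estimated correlation), with Oas1a at 1.03 and Oas2 at 0.96, and antigen presentation 0.22 (adjusted p = 1.65e-04, and 0.636 with an estimated correlation), with H2-Eb1 at 0.44 and H2-DMa at 0.55. T and NK cell genes had 0.39 (adjusted p = 0.00274) and progenitor genes 0.12 (adjusted p = 0.0283), both with an adjusted p = 0.608 with an estimated correlation, and Ccr7 (2.58), Lck (0.68), Pdgfra (0.42) and Ly6a (0.57) led them. Inflammation genes had 0.17 (adjusted p = 0.0208, and 0.719 with an estimated correlation), with Icam1 at 0.59 and Tnf at 1.60, and cell cycle genes 0.27 (adjusted p = 0.0138, and 0.775 with an estimated correlation), with Aurkb at 0.50 and Rrm2 at 0.57. Adjusted over the list alone, the inflammation, T and NK cell and progenitor lists held 1 higher gene each, and the other lists named above 0. Lower lists were skeletal muscle (-6.01, adjusted p = 4.92e-20, and 0.477 with an estimated correlation, 18 of 18 lower when adjusted over the list alone, with Myh1 at -5.04 and Neb at -6.02) and circadian genes (-0.26, adjusted p = 0.0255, and 0.739 with an estimated correlation, with Cry1 at -0.59 and Per2 at -0.55). Mitochondrially encoded genes (-0.25, adjusted p = 0.0275), the nuclear respiratory chain (-0.08, adjusted p = 0.0283) and lipogenesis (-0.20, adjusted p = 0.0305) were also lower, each with an adjusted p = 0.882 with an estimated correlation, and mt-Atp6 had -0.61, mt-Nd3 -0.36, Cycs -0.39, Ndufv2 -0.25, Mlxipl -0.29 and Acaca -0.51. None of the genes named for these lists passed over all genes, and by fry 0 lists were called, in 1 direction or in either.

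Of these lists, 8 lost their call in Homo KO against Hete KO when the muscle-transcript libraries, Hete KO 2 among them, were left out. They were antigen presentation (0.05), cell cycle (0.07), circadian (-0.06), inflammation (0.16), pro-angiogenic (0.05), progenitor (0.10), respiratory chain (0.00) and T and NK cell genes (0.25). The skeletal muscle median was still -2.64 in that fit, so the groups still differed in muscle transcripts. Leaving out Hete KO 2 alone ended the calls of antigen presentation (0.06), cell cycle (0.08), circadian (-0.05), inflammation (0.13), mitochondrially encoded (-0.17), pro-angiogenic (0.06), progenitor (0.11), respiratory chain (0.01) and T and NK cell genes (0.26), and camera then called 9 lists in place of 16. Leaving out Homo KO 1 ended those of endothelial (0.02), anti-angiogenic (0.14), cell cycle (0.14), circadian (-0.27), inflammation (-0.09), lipogenesis (-0.03), mitochondrially encoded (-0.18), pro-angiogenic (0.07), progenitor (0.09) and respiratory chain genes (0.02). The mitochondrially encoded (-0.20) and pro-angiogenic (0.11) calls ended without Hete KO 3, the progenitor (0.15) and T and NK cell (0.25) calls without Homo KO 3, the circadian call (-0.20) without Homo KO 2 and the lipogenesis call (-0.11) without Hete KO 1. With the length offset 11 lists were called. The respiratory chain (-0.05), lipogenesis (-0.16), pro-angiogenic (0.10), anti-angiogenic (0.17) and circadian (-0.23) calls ended. The respiratory chain, progenitor and circadian calls also ended with 1 surrogate variable (-0.04, 0.01 and -0.08) and with the muscle and liver covariates (-0.05, -0.02 and -0.10). The covariates ended the T and NK cell call (0.21) as well and turned the skeletal muscle median to 0.12. Without the liver-transcript libraries the inflammation (0.17) and progenitor (0.12) calls ended. Lists whose median was above 0 with a mean below 0 were cholesterol synthesis (0.05 and -0.01), hypoxia (0.00 and -0.08), mural cells (0.12 and -0.06) and heat shock (0.02, mean just below 0), none of them called.

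None of the 8 fixed genes passed in Homo KO against Hete KO. Lep had a log2 fold change of 0.31 (SE 0.209, adjusted p = 0.936), Pecam1 0.27 (adjusted p = 0.913), Thbs1 0.32 (adjusted p = 0.959) and Vegfa -0.23 (adjusted p = 0.936). Ucp1 had -1.39 (adjusted p = 0.967), Cidea -0.34 (adjusted p = 0.987), Ppargc1a -0.18 (adjusted p = 0.982) and Adipoq 0.04 (adjusted p = 0.998). Without Hete KO 2 these 4 values were 1.25, 0.25, 0.16 and -0.05, and without Homo KO 3 that of Adipoq was -0.04.

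Fold changes against WT were compared between the knockout groups to ask whether the same genes differ in both. The 75 genes called in Hete KO had the same sign in Homo KO in all 75 cases, 72 of them with an unadjusted p under 0.05 there, Ass1, Hapln4, Nnat and Gulp1 among them, and none of the 75 passed in Homo KO against Hete KO. Both comparisons use the same 3 WT libraries, which by itself makes fold changes alike. The simulations below drew each gene on its own, with the same spread for all libraries. They hold no transcripts that rise together in single WT libraries, as muscle and liver transcripts did here. Their ranges therefore cannot show all that shared WT libraries give without a group difference. In 20 simulations without any group difference, the 75 genes with the smallest p in Hete KO had the same sign in Homo KO in 69 cases on average (65 to 74), and 32.2 of them also had an unadjusted p under 0.05 there (22 to 39). At an unadjusted p under 0.05 in both, 953 genes were higher in both knockout groups, 986 were lower in both and 2 went opposite ways, against 112, 74.5 and 2.70 in the simulations and 135 higher and 190 lower for independent lists. Across 17968 genes, which are not independent replicates, the Pearson correlation of the log2 fold changes was 0.566, and 78.7% of genes had the same sign. In the simulations the correlation averaged 0.493, between 0.453 and 0.531, with 66.6% of genes of the same sign. With the stricter filter the correlation was 0.522, and over genes of at least 10 CPM 0.486, both inside the simulated ranges of 0.443 to 0.537 and 0.413 to 0.541. In those 2 sets of genes the correlation by itself did not set the data apart from unchanged groups. The covariance was 0.332, against 0.103 in those simulations, a difference of 0.229. It was 0.223 against 0.0792 with the stricter filter and 0.121 against 0.0358 over genes of at least 10 CPM. In a check chosen after the data were seen, the WT libraries were divided between the comparisons, 1 and 2, in all 6 ways. The correlation then ran from -0.0674 to 0.330 and the covariance from -0.0699 to 0.304. How alike the fold changes were depended on which WT library served which group.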

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

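The settings for muscle and liver transcripts, the divided WT libraries and all values for both KO groups together against WT were chosen after the data were seen, and all other settings before. Ago1 kept its direction against WT in every setting, with log2 fold changes between -0.63 and -0.10 in Homo KO (adjusted p between 0.349 and 0.966) and between -0.30 and -0.08 in Hete KO (adjusted p between 0.358 and 0.947). Leaving out 1 library at a time gave -0.63 to -0.11 for Ago1 in Homo KO, -0.25 to -0.11 in Hete KO and -0.44 to 0.074 between Homo KO and Hete KO, where 0.074 came without Homo KO 3. The counts of genes varied more. For Hete KO against WT, where 27 genes were higher and 48 lower, DESeq2 gave 599 and 1011, upper-quartile normalization 25 lower, no filter 90 and 168, the stricter filter 41 higher, the length offset 0 and 1, the fit of the 2 groups only 0 and 0, the replicate block 92 and 156, 1 surrogate variable 73 and 124, limma on log2 TPM 0 and 0 with a pseudocount of 0.5 and 4 and 0 with 0.1, and the robust fit 118 and 186. It was 1 and 10 without the muscle-transcript libraries, 1 and 0 without the liver-transcript libraries, 0 and 0 with both as covariates, and 0 to 357 higher and 0 to 601 lower without each library in turn. Whether the replicate numbers pair the samples is not known. After removal of group means, libraries of different groups with the same number had correlations from -0.0722 to 0.458 (median 0.047). Those with other numbers ran from -0.455 to 0.251 (median -5.8e-05). For Homo KO against WT, where 0 were called, DESeq2 gave 271 and 362, no filter 1 lower, the fit of the 2 groups only 7 lower, 1 surrogate variable 2 lower, the fit without muscle-transcript libraries 3 and 38, the fit without liver-transcript libraries 1 and 1, and leaving out each library 0 to 19 higher and 0 to 134 lower. For Homo KO against Hete KO, where 0 were called, DESeq2 gave 2 lower and limma with a pseudocount of 0.1 gave 2 higher and 4 lower, while leaving out each library gave 0 to 0 in both directions. For both KO groups together, where 148 were higher and 273 lower, upper-quartile normalization gave 163 lower, no filter 223 and 536, the length offset 0 and 4, 1 surrogate variable 90 higher, DESeq2 739 and 1049, limma 3 and 3 with a pseudocount of 0.5 and 0 and 0 with 0.1, the fit without muscle-transcript libraries 5 and 97, that without liver-transcript libraries 1 and 1, the covariates 0 and 1, and leaving out each library 0 to 393 higher and 2 to 702 lower. The lists called by camera numbered 15 in Homo KO against WT (0 with an estimated correlation, 0 by fry, 9 with the covariates, 12 to 18 without each library), 15 in Hete KO against WT (0 with an estimated correlation, 4 by fry, 9 to 18 without each library), 16 in Homo KO against Hete KO (0 with an estimated correlation, 0 by fry, 10 without muscle-transcript libraries, 9 to 17 without each library) and 16 in both KO groups against WT (0 with an estimated correlation, 4 by fry, 10 without muscle-transcript libraries, 11 to 18 without each library). The correlation of fold changes, 0.566, was 0.652 with 1 surrogate variable, 0.664 by limma with a pseudocount of 0.5, 0.486 over genes with a mean of at least 10 CPM, 0.783 without muscle-transcript libraries, 0.673 without liver-transcript libraries, 0.715 with the covariates and 0.528 to 0.750 without each library. With WT 1, WT 2 or WT 3 alone for Homo KO and the other 2 for Hete KO it was -0.00014, 0.286 and 0.330, and with each alone for Hete KO 0.116, 0.295 and -0.067. Some log2 fold changes changed sign. With 1 surrogate variable this held in Homo KO against WT for Thbs1 (0.36), Ucp1 (0.93), Cidea (0.76) and the skeletal muscle list (0.13), and in Homo KO against Hete KO for Ucp1 (3.33), Cidea (0.44), Ppargc1a (0.16) and Adipoq (-0.28). Cidea, close to 0 in Homo KO against WT, was 0.0040 by DESeq2, 0.0024 with RLE factors, 0.0078 with upper-quartile normalization, 0.00060 with the stricter filter, 0.0029 with the length offset, 0.38 with the replicate block, 0.42 and 0.45 by limma with pseudocounts of 0.5 and 0.1, 0.013 without Hete KO 1, 0.012 without Hete KO 3, 0.31 without Homo KO 1, 1.22 without WT 2 and 1.95 without the liver-transcript libraries. Without those libraries Ucp1 in Hete KO against WT was 0.86. Without the muscle-transcript libraries, Homo KO against WT gave 0.57 for Thbs1, 1.86 for Ucp1, 0.74 for Cidea, -0.080 for Adipoq, 1.33 for Tnnc2, 0.83 for Ckm and 1.54 for the skeletal muscle list. Hete KO against WT then gave 0.041 for Thbs1, 0.60 for Ucp1, 0.044 for Pecam1, -0.019 for Adipoq and -0.092 for the respiratory chain list, and Homo KO against Hete KO 1.26 for Ucp1, 0.24 for Cidea, 0.15 for Ppargc1a and -0.062 for Adipoq. With the covariates, Homo KO against WT gave 0.28 for Thbs1, 3.71 for Ucp1, 2.38 for Cidea, -0.037 for the B cell list and -0.082 for the skeletal muscle list, and Homo KO against Hete KO 3.83 for Ucp1, 0.75 for Cidea, 0.034 for Ppargc1a, -0.35 for Adipoq and 0.12 for the skeletal muscle list. Leaving out each library in turn, Homo KO against WT ran from -0.44 to 0.081 (without WT 1) for Thbs1, from -4.43 to 0.23 (without WT 2) for Ucp1, from -0.44 to 1.22 for Cidea and from -0.0084 (without Homo KO 1) to 0.23 for Pecam1. Hete KO against WT ran from -5.08 to 1.64 (without WT 2) for Ucp1 and from -0.26 (without Hete KO 2) to 1.57 for Cidea, which was -0.092 without WT 1. Homo KO against Hete KO ran from -2.01 to 1.25 for Ucp1, from -0.58 to 0.25 for Cidea, from -0.35 to 0.16 for Ppargc1a and from -0.050 to 0.12 for Adipoq, with the reversed ends without Hete KO 2, and Adipoq was also -0.042 without Homo KO 3. There the respiratory chain list ran from -0.18 to 0.015, positive without Homo KO 1 and, at 0.013, without Hete KO 2, and lipogenesis from -0.31 to -0.027, the latter without Homo KO 1, where its test pointed up. The fits that leave out libraries use fewer samples, the fit without muscle-transcript libraries leaves 1 WT library and that without liver-transcript libraries leaves WT 1, whose spread is taken to be that of the other groups. For all other changes the cause was not tested. Among the other single genes and lists, 4495 values kept their direction and their side of the threshold, 863 lost a call and 141 gained one.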

Other observations

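The comparison of both KO groups together with WT, the liver list, the tests of muscle and liver transcripts, of the make-up of the lists and of genes near Ago1, and the splits of 3 against 3 libraries were chosen after the results were seen, and the splits of 6 against 3 libraries after that comparison but before their own counts. With the 6 KO libraries set against the 3 WT libraries, edgeR called 148 genes higher and 273 lower, with 4057 at an unadjusted p under 0.05. Ass1 fell with a log2 fold change of -3.00 (SE 0.258, adjusted p = 0.00395) and Hapln4 with -2.71 (SE 0.231, adjusted p = 0.00395), each lower in 6 of 6 KO libraries than in any WT library. The rule for named genes required this separation. Bmp1 fell with -0.81 (adjusted p = 0.0155), Serpina3m with -2.14, Hist1h2af with -1.70 and Slc6a6 with -1.05 (adjusted p = 0.0228 each). Tfr2, which encodes transferrin receptor 2, had -2.03 (adjusted p = 0.0258), and Tmem132b and Cenpe had -3.24 and -1.47 (adjusted p = 0.0265). Over the settings the value of Tfr2 ran from -2.17 to -0.89. Gulp1 rose by 0.998 (adjusted p = 0.0228), and Nnat by 1.49, Slc44a3 by 0.88, Pcf11 by 0.71, Thap2 by 0.76 and Snhg11 by 0.91 (adjusted p = 0.0258 each). Lama3, Zfp809, Rad9b and Zfp970 rose by 1.06, 0.96, 1.26 and 0.93 (adjusted p = 0.0265). The call counts rest on single libraries. They were 236 higher and 514 lower without WT 1, 0 and 3 without WT 2, 27 and 24 without WT 3, 393 and 702 without Hete KO 1, 54 and 183 without Hete KO 2, 0 and 2 without Hete KO 3, 24 and 29 without Homo KO 1, 0 and 2 without Homo KO 2 and 0 and 3 without Homo KO 3. They were 5 and 97 without the muscle-transcript libraries, with 44 of the 421 genes shared, 1 and 1 without the liver-transcript libraries and 0 and 1 with both as covariates.

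Several groups of genes held members past the threshold over all genes in this comparison. Pck1, of the triglyceride storage and lipolysis list, rose from 1157 ± 454 CPM in WT to 3232 ± 860 in Hete KO and 3476 ± 783 in Homo KO (1.53, SE 0.298, adjusted p = 0.0411), while Pnpla2, the adipose triglyceride lipase, had 0.72 (adjusted p = 0.0726). Cholesterol synthesis held 5 lower genes over all genes and 9 lower and 1 higher adjusted over the list alone, with Fdps at -0.72 (adjusted p = 0.0411). Among pro-angiogenic genes, Vegfb rose by 0.67 (adjusted p = 0.0410) and Angpt1 by 1.20 (adjusted p = 0.0436), the latter a ligand of the endothelial receptor Tie2. Of the macrophage list 18 of 22 genes were lower adjusted over the list alone and 3 over all genes, with C1qc at -0.89 (adjusted p = 0.0395) and C1qa at -1.02 (adjusted p = 0.0398). In the cell cycle list these counts were 15 of 20 and 5, with Aurkb at -1.45 (adjusted p = 0.0265) and Cenpf at -1.03 (adjusted p = 0.0382), and in the matrix list 17 of 28 and 3, with Fn1 at -1.15 (adjusted p = 0.0395) and Col12a1 at -1.95 (adjusted p = 0.0411). The progenitor list held 9 lower and 1 higher adjusted over the list alone, and 4 lower and 1 higher over all genes, with Dpp4 at -1.20 (adjusted p = 0.0265) and Sfrp4 at -1.25 (adjusted p = 0.0382). Other genes past the threshold were Slc36a2, a beige-selective amino acid transporter (-0.56, adjusted p = 0.0395), the hypoxia gene Pfkfb4 (-0.71, adjusted p = 0.0436), Lcn2 (-2.23, adjusted p = 0.0398), H2-DMb1 (-1.59, adjusted p = 0.0265), Cr2 (0.94, adjusted p = 0.0408), the skin gene Perp (-2.98, adjusted p = 0.0378) and the circadian repressor gene Nfil3 (-1.27, adjusted p = 0.0477). By camera 16 lists were called, with an estimated correlation 0, and by fry 4, namely cholesterol synthesis (adjusted p = 0.0473) and the progenitor, heat shock and cell cycle lists (adjusted p = 0.0299 each). With 1 score per library, the mitochondrially encoded, cholesterol synthesis, progenitor, heat shock and cell cycle lists separated all 6 KO from all 3 WT libraries, each at an exact permutation p of 0.0119, the smallest that 84 arrangements can give. Adjusted over the 36 lists that p was 0.0857, so no list passed. The matrix, blood, neutrophil and mast cell, and antigen presentation scores also lay lower in all 6 KO libraries than in any WT library. Their exact permutation p, which rests on the difference of mean scores, was 0.0357, 0.0238, 0.0476 and 0.0595.

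Skeletal muscle transcripts stood out in WT 1, WT 2 and Hete KO 2, and liver transcripts in WT 2 and WT 3. The muscle genes kept nearly the same proportions in different libraries, since their log2 ratios between Hete KO 2 and WT 1 had an SD of 0.428 over 18 genes, as muscle tissue in these samples would give. The AGO1 genotype was argued against as the source, because the muscle list's share differed 84.7-fold between libraries of the Hete KO group. For the liver genes the log2 ratios between WT 2 and WT 3 had an SD of 0.559 over 24 genes, which is consistent with liver RNA or reads in both libraries, and the share differed 48.8-fold within the WT group, which argues against genotype. Whether the RNA entered at dissection, extraction or sequencing stays open.

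By camera at the preset correlation, macrophage, matrix and cell cycle lists were lower, and adipocyte and mitochondrially encoded lists higher, in the KO groups. None of these calls held with an estimated correlation. The macrophage score fell farther than the endothelial score (difference between KO and WT libraries -0.854, exact permutation p = 0.0119). Both lists were picked after their results were seen, and endothelial cells are the knockout target. The test therefore cannot exclude a smaller share of all non-adipocyte cells as the cause. For the 3 lower lists in Hete KO, muscle or liver RNA in the WT libraries was tested with both scores as covariates. All 3 stayed called (though not with an estimated correlation, adjusted p = 0.364 without and 0.605 with the covariates), at 0.909, 0.916 and 0.921 of their medians. The 95% interval of their mean score lay just below 0 (-1.93 to -0.0159). The fit takes a common slope for all groups, but the macrophage score ran opposite ways with muscle transcripts. It was 5.36 and 5.46 in the muscle-rich WT 1 and WT 2 and 4.58 in WT 3. Within Hete KO it was lowest, at 3.66, in the muscle-rich Hete KO 2. The covariates therefore cannot decide the question. With WT 3 as the only WT library the medians shrank to -0.40, -0.45 and -0.54, at a skeletal muscle median of 4.45. In Homo KO the matrix and cell cycle lists stayed called with the covariates, at 1.004 and 0.753 of their medians, though not with an estimated correlation (adjusted p = 0.933). Without the muscle-transcript libraries their medians were -0.20 and -0.40, against -0.37 and -0.72 with all libraries. The macrophage call ended with the covariates, at 0.347 of its median. The interval of the mean score of the 3 lists ran from -1.20 to -0.000897 without the covariates and from -1.62 to 0.801 with them. For the adipocyte and mitochondrially encoded lists the interval with the covariates reached -0.224 in Hete KO and -0.827 in Homo KO. For these and for the lower lists in either KO group, such RNA and the genotype cannot be told apart with 3 WT libraries. A change in single cell types with the genotype stays open and was not tested.

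The genes called within 10 Mb of Ago1 on chromosome 4 were counted, since variants linked to the targeted allele could change genes there. Of 294 tested genes in the window, 3 of the 75 called in Hete KO against WT lay inside, with an odds ratio of 2.52 (95% interval 0.505 to 7.74, Fisher's exact p = 0.125). Of the 421 called in both KO groups against WT, 7 lay inside, with an odds ratio of 1.02 (interval 0.403 to 2.14, exact p = 0.846). Both intervals include an excess and a deficit, so linked variants and none cannot be told apart.

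Other splits of the same libraries were fitted in the same way. Splits of 3 against 3 libraries number 10 per comparison, too few for a share under 0.05. In Homo KO and WT, the real split called 0 genes and the highest other 0, so all 10 of 10 gave as many, and 15 lists against 18, with 2 splits at or above the real value. In Hete KO and WT, the real split called 75 genes and the highest other 222, with 2 splits at or above the real value, and 15 lists against 20, with 3 splits. The split with 222 genes set WT 1, WT 2 and Hete KO 2, the muscle-transcript libraries, against the rest, which points to a structure of the samples. In Homo KO and Hete KO, the counts were 0 genes against 0, with 10 splits, and 16 lists against 18, with 4 splits. For both KO groups against WT, fitted as 2 groups, 1 of 84 splits, the real split, gave as many as 423 genes. That grouping was itself chosen after the data were seen, so this count of splits does not exclude chance. The next split, again WT 1, WT 2 and Hete KO 2 against the rest, gave 381. For lists 20 of 84 splits gave at least the real 15, with 24 as the highest other, so chance cannot be excluded there.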
